A study of Homo sapiens with 6 samples.

How the data were processed

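Total RNA from 3 OMT-treated and 3 untreated HGC-27 cultures was transcribed into Cy3-labelled cRNA and hybridised to custom single-colour Agilent human arrays, per the labels' protocols. Images were read with Agilent Feature Extraction, per the submitters' processing notes, whose version is not given in the sources used here. The series text says that the values were normalized, without a method. The deposited values are log2 intensities: the scale is not stated, and base 2 was taken from their range of 0.88 to 18.9, which other usual bases would carry past any scanner. All 6 columns matched a sample by the labels, and 0 columns were left unmapped. Scanner files, background flags and scan batches were not analysed here, so a slide or a scan could not be tested as a batch. The number of arrays limits the precision.

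The sorted values were identical among the 3 arrays of each group and differed between the groups, which is what quantile normalization of each group by itself would give. Such a step keeps the order of probes within an array. Quantile normalization over all 6 arrays ranks the probes by that order and gives every array the mean of the 6 deposited distributions. The sizes of change after it therefore depend on the deposited values as well. It forces the groups to one distribution, so it would also remove a true change of most RNAs in one direction.

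The 68 control spots were left out of the tests of RNA probes and examined separately. Probe families were read from the form of the probe IDs. Neither the deposited table nor the gene tables at hand paired a probe ID with a gene, so 0 genes could be named for RNA probes. The gene-level test and the gene lists fixed before the data were examined could not be run for that reason, nor could counts for mRNA and long noncoding RNA. No host gene was assigned to a circRNA.

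Groups were compared per probe on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment as the only term), two-sided, with Benjamini-Hochberg adjustment over 175075 probes and a threshold of 0.05. Medians per array were compared with exact two-sided permutation tests over the 20 labelings of 3 against 3 arrays, which cannot go below p = 0.1. The signal of the dark corner spots on each array served as a floor, since no detection flags were at hand. A total of 105970 probes lay above it on all 3 OMT arrays and 111669 on all 3 control arrays. A probe at or below it on every array of a group is given as a bound.

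Named probes were chosen by a rule fixed before the data were examined. A probe qualified if its mean was above the median of all probes, its groups did not overlap and its adjusted p was below 0.05, which held for 61936 probes and 28975 circRNA probes. The 2 largest rises and the 2 largest falls were named over all probes, and again over circRNA probes.

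Alternatives fixed at the same time were quantile normalization over all 6 arrays, centring on the 75th percentile, leaving out the lowest 25% or 50% of probes by mean, a replicate block, each array left out in turn, eBayes with trend and robust fitting, array weights, an adjusted p below 0.01 and an added 2-fold threshold. Comparisons at matched levels and by the numbers inside probe IDs were added after the data were seen.

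The fit was tested on simulated arrays of 175075 probes with 200 changed ones. It made 1 false call and recovered 9% of the 2-fold and 49% of the 4-fold changes. With only 200 changed probes, drawn from those above the median, the adjustment is stricter than where many probes change. These shares are therefore not the recovery to expect in the deposited data. Quantile normalization of the simulated arrays within each group made 2 false calls. In the same simulation, each group's ranks were also given that group's deposited distribution, whatever made the distributions differ. Of the unchanged probes, 86997 were then called, 99.7% of them lower in OMT. Figures were drawn with matplotlib 3.10.9.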

Results

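RNA was measured in 6 cultures of HGC-27, an established human gastric cancer cell line. 3 cultures were treated with oxymatrine (OMT), an alkaloid of Sophora roots, at 2.64 mg/mL for 48 h, and 3 were left untreated as controls. The series describes the 3 samples of each group as biological replicates. Labelled RNA was hybridised to single-colour Agilent arrays designed to read mRNAs, long noncoding RNAs and circular RNAs (circRNAs, closed RNA rings formed by back-splicing). Each array gave 175143 values, of which 175075 belonged to RNA probes and 68 to control spots. The RNA probes fell by their IDs into 47899 circRNA probes (35343 with circBase IDs and 12556 with CIRCpedia IDs), 122475 probes named by a cluster number, and 4701 Agilent catalogue probes. The IDs were not paired with gene names in the tables used here, so RNAs are reported by probe ID and family, and mRNAs and long noncoding RNAs could not be counted separately.

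The deposited log2 values of the 6 arrays did not share one distribution. Sorted from low to high, the 175143 values were identical on the 3 OMT arrays, with a largest difference of 0, and identical on the 3 control arrays, but they differed by up to 1.57 between the groups. The median was 2.97 on each OMT array and 3.97 on each control array, and the 75th percentile was 6.13 against 6.93. Treatment and normalization set therefore cannot be told apart in the deposited levels. Counts are given for the values as deposited and after quantile normalization over all 6 arrays together (joint normalization). Across probes, Pearson's r was 0.978 to 0.981 between OMT arrays, 0.988 to 0.989 between control arrays and 0.926 to 0.930 between an OMT and a control array. Over the 87537 probes with a mean above the median, the median SD between replicates was 0.21 in OMT and 0.10 in controls, on the log2 scale.

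**Figure D1:**
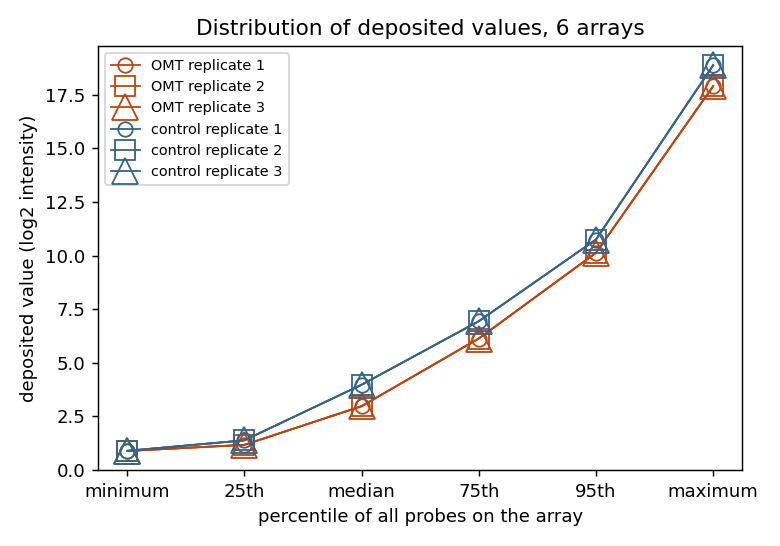
Minimum, 25th percentile, median, 75th and 95th percentiles and maximum (x axis) of the deposited log2 values (y axis) of each array, OMT in orange and control in blue, with a marker shape per replicate. The 3 arrays of a group lie on one another, with medians of 2.97 in OMT and 3.97 in controls.

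The comparison of treated with untreated cultures asked which mRNAs, long noncoding RNAs and circRNAs differ after OMT. As deposited, 81099 of the 175075 RNA probes (46.3%) differed at an adjusted p below 0.05 (limma, Benjamini-Hochberg, n = 3 per group), 13808 of them higher and 67291 lower in OMT. At least 2-fold changes were found for 6532 higher and 47786 lower probes. After joint normalization, 68940 probes differed, 36149 higher and 32791 lower, and at least 2-fold changes were found for 20757 higher and 22506 lower probes. Centring each array on its 75th percentile gave 74360 higher and 35517 lower probes. The share of called probes that were lower was thus 83.0% as deposited, 47.6% after joint normalization and 32.3% after centring. The median change of all probes was -0.36 as deposited, 0.04 after joint normalization and 0.44 after centring.

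The direction of 46598 probes was called alike as deposited and after joint normalization, 13807 of them higher and 32791 lower in OMT. A further 2321 probes were called lower as deposited and higher after joint normalization, and 0 probes went the other way. The 3 OMT and 3 control values did not overlap for 60.4% of the RNA probes as deposited and for 53.6% after joint normalization, where chance gives 10% on arrays that share one distribution. Simulated unchanged probes that were given the deposited distribution of each group did not overlap in 58.4% of cases. Control spots without a human gene name also differed between the groups. Among 10 E1A spike spots, 6 differed as deposited and 8 after joint normalization, and among 18 DCP spots, 9 and 12. Among 25 ERCC and ETG spots, 11 differed as deposited and 5 after joint normalization, all 5 lower in OMT. Of these 5, 4 were among the 7 spots above the dark corner spots on all 6 arrays and 1 was among the other 18.

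CircRNA probes were lower in OMT more often than higher under each of the 3 scalings. As deposited, 32533 of the 47899 circRNA probes (67.9%) differed, 2895 higher and 29638 lower in OMT. After joint normalization 26690 differed, 10525 higher and 16165 lower, and after centring 14783 were higher and 16958 lower. The probes with circBase IDs and those with CIRCpedia IDs had 61.0% and 59.3% of their called probes lower after joint normalization. The median level of the circRNA probes after joint normalization was 6.00 ± 0.04 in OMT and 6.22 ± 0.01 in controls (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The median level of the cluster probes was 2.52 ± 0.03 in OMT and 2.38 ± 0.003 in controls after joint normalization, but 2.11 ± 0.03 and 2.77 ± 0.003 as deposited, so the direction of this family depended on the scaling. Of the cluster probes, 10328 were called higher and 35707 lower as deposited, against 24301 higher and 15674 lower after joint normalization. The Agilent catalogue probes likewise went from 585 higher and 1946 lower to 1323 higher and 952 lower.

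At matched levels, circRNA probes stood below cluster probes in OMT relative to controls. Among probes with a mean level from 6 up to 8 after joint normalization, the median change was -0.07 for 13711 circRNA probes, 0.37 for 10960 cluster probes and 0.06 for 681 Agilent catalogue probes. The catalogue probes thus lay between the other families at these levels, but not at every level. At levels from 2 up to 4, the medians of catalogue, cluster and circRNA probes were 0.11, -0.003 and -0.96. At levels from 4 up to 6 they were 0.27, 0.29 and -0.29. Relative to catalogue probes at levels from 6 up to 8, circRNA probes differed by -0.15 and cluster probes by 0.24 between OMT and controls. Each of these 2 differences had an exact two-sided permutation p of 0.1. The circRNA median minus the cluster median on an array was -0.16 ± 0.05 in OMT and 0.24 ± 0.01 in controls (SD, n = 3), a difference of -0.40 with an exact two-sided permutation p of 0.1. The same difference was -0.08 at levels below 2, -0.93 at levels from 2 up to 4, -0.61 from 4 up to 6, -0.40 from 8 up to 10, -0.43 from 10 up to 12 and -0.16 at 12 or more, where circRNA medians lay below cluster medians in controls as well (-0.34). The exact p was 0.1 in each of the 7 level ranges, before and after Benjamini-Hochberg adjustment over them. The changes of circRNA probes also varied with a number in the probe ID whose meaning is not given in the sources used here. At levels from 6 up to 8, probes with 0 as the next-to-last number had a median change of 0.37, and those with 16 had -0.42.

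**Figure D2:**
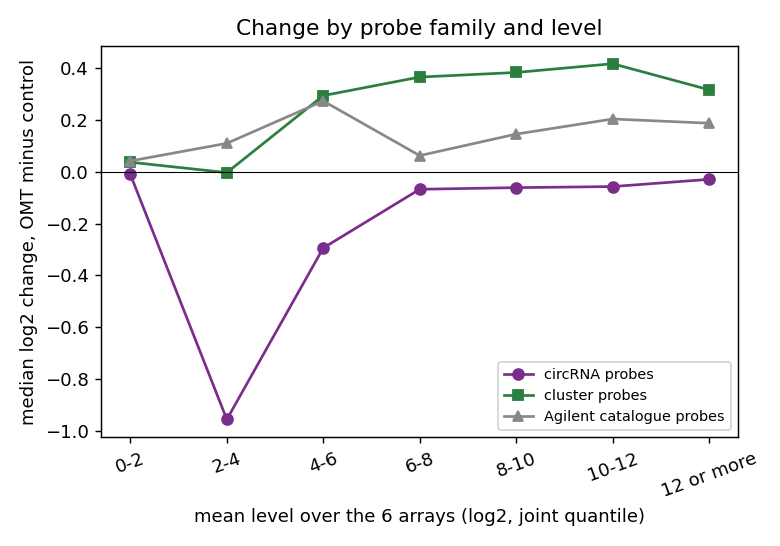
Median log2 change, OMT minus control (y axis), of circRNA probes, cluster probes and Agilent catalogue probes by mean level over the 6 arrays (x axis, log2), after joint normalization. From level 4 on, cluster medians lie above 0 and circRNA medians below 0 on this scaling, for example 0.37 and -0.07 at levels from 6 up to 8.

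The signals of single circRNA probes differed by large factors in both directions. The next-to-last numbers of the named probes were 16 and 9 for the falls and 0 and 7 for the rises, and whether the probes also read linear RNA is not stated in the sources used here. As deposited, the probe hsa_circ_0033035_16_31 had a level of 2.81 ± 0.73 in OMT and 10.90 ± 0.05 in controls (SD, n = 3), a log2 change of -8.09 with a limma adjusted p of 7.4e-05. The level of hsa_circ_0076919_9_38 was 7.71 ± 0.37 in OMT and 15.23 ± 0.13 in controls, a change of -7.52 (adjusted p 3.0e-05). In the other direction, hsa_circ_0135574_0_35 stood at 6.67 ± 0.86 in OMT and 2.003 ± 0.97 in controls, a change of 4.66 (adjusted p 0.0028), with 1 control array at or below the dark corner spots. The level of hsa_circ_0085384_7_17 was 6.48 ± 0.77 in OMT and 2.16 ± 0.43 in controls, a change of 4.32 (adjusted p 9.0e-04). Relative to the median change of all probes, these 4 changes were -7.72, -7.15, 5.03 and 4.68. After joint normalization they were -7.31, -6.64, 5.29 and 5.01.

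Over all families, the probes with the largest falls and rises under the rule fixed before the data were examined were cluster probes. The level of clstr_229025_20_17 was 1.57 ± 0.56 in OMT and 12.31 ± 0.09 in controls (SD, n = 3), a log2 change of -10.75 (limma adjusted p 3.0e-05), and that of clstr_207485_20_16 was 1.26 ± 0.16 and 11.87 ± 0.12, a change of -10.61 (adjusted p 2.6e-05). They were at or below the dark corner spots on 1 and 2 of the 3 OMT arrays. The level of clstr_183834_239_13 was 7.76 ± 0.44 in OMT and 2.26 ± 0.62 in controls, a change of 5.50 (adjusted p 2.4e-04), with 1 control array at or below the dark corner spots. On all 3 control arrays clstr_55622_544_5 was at or below the dark corner spots, so its level of 6.57 ± 0.09 in OMT against 1.17 ± 0.05 was at least 30.9-fold higher in OMT (adjusted p 2.6e-05). Relative to the median change of all probes, the changes of the first 3 of these probes were -10.38, -10.25 and 5.87. All 8 named probes kept their direction and an adjusted p below 0.05 under every setting in which they were refitted. They were picked for the largest changes on these same arrays, so this is not independent support.

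GAPDH and PGK1, which encode glycolytic enzymes, were the only human genes named in the tables used here, with a pair of control spots each. The spot Human-GAPDH_3 read 16.50 ± 0.05 in OMT and 18.14 ± 0.05 in controls (SD, n = 3), a log2 change of -1.64 (limma adjusted p 6.4e-05), or -0.17 after joint normalization. Human-GAPDH_5 differed by -0.17 as deposited (adjusted p 0.227) and by 1.05 after joint normalization. For PGK1, Human-PGK1_3 differed by 0.24 (adjusted p 0.0307) and Human-PGK1_5 by 0.04 (adjusted p 0.838) as deposited, against 1.42 and 0.65 after joint normalization. The spots of one gene differed from each other in their changes, and the direction of GAPDH depended on the spot and the scaling. The bright corner spots, whose name does not state a target, moved by -1.65 as deposited and by -0.17 after joint normalization, close to Human-GAPDH_3. Their deposited levels, 16.46 in OMT and 18.11 in controls, were close to that spot as well, so they may read cell RNA.

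**Figure D3:**
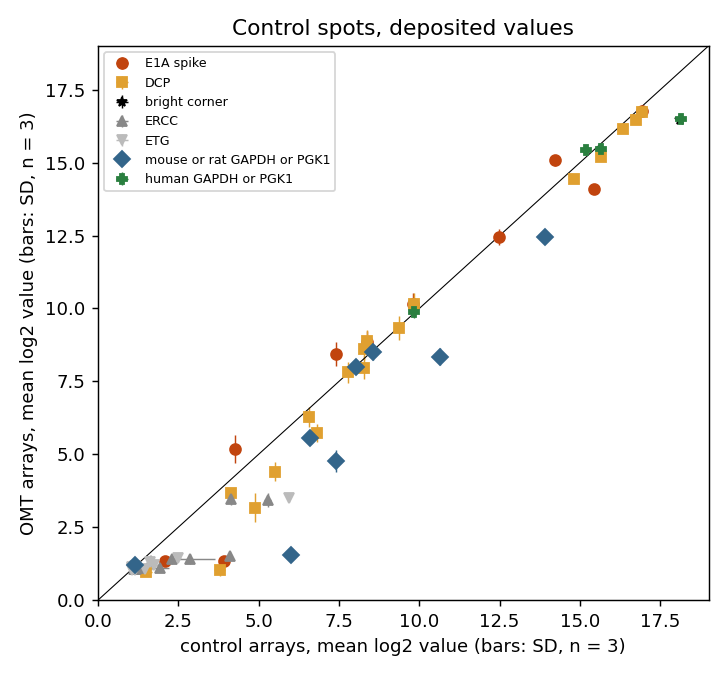
Mean deposited log2 value of control spots on the 3 control arrays (x axis) and the 3 OMT arrays (y axis). Bars show the SD, the line marks equal values, and the DarkCorner and (-)3xSLv1 spots are not drawn. Mouse-PGK1_3 lies farthest from the line, at 6.02 in controls and 1.55 in OMT.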

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

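The fits that called RNA probes between OMT and control, as deposited and after joint normalization, were fixed before the data were examined. The other tests in this part were chosen after the results they bear on had been seen. The control spots lie outside the comparison of RNA probes, and 4 of them were called higher in OMT as deposited. The E1A spike spots a107, a135 and n11 differed by 0.93, 1.04 and 0.86 (log2, OMT minus control), and Human-PGK1_3 by 0.24. Other spots were far lower in OMT. The level of the E1A spot r60_3 was 1.36 ± 0.06 in OMT and 3.92 ± 0.13 in controls (SD, n = 3), and that of Mouse-PGK1_3 was 1.55 ± 0.11 and 6.02 ± 0.05. Mouse-GAPDH_3 and Mouse-GAPDH_5 differed by -2.31 and -2.65 as deposited and by -1.68 and -1.80 after joint normalization. For these 2 scalings, Human-GAPDH_3 differed by -1.64 and -0.17, and Human-GAPDH_5 by -0.17 and 1.05. Of the 8 mouse and rat spots, 6 were called after joint normalization, 4 lower and 2 higher in OMT. E1A n11 minus n9, a pair singled out after its values were seen, was 0.97 ± 0.08 on OMT arrays and -1.23 ± 0.03 on control arrays (SD, n = 3), a difference of 2.20.

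As deposited 81099 RNA probes were called, and 68940 after joint normalization. Normalizing each group by itself keeps the order of probes within an array, so it cannot be the only cause: Spearman's rho over the 175075 RNA probes was 0.870 to 0.883 between an OMT and a control array and 0.914 to 0.968 within a group. After joint normalization 69.2% of the 26 E1A, DCP, bright corner, ERCC and ETG spots with a level of 4 or more were called (16 higher, 2 lower), against 66.6% of 77934 RNA probes of that level, and 46.3% of all 54 such spots (17 higher, 8 lower). These spots are not independent: as deposited, DCP_20_0 read 8.89 in OMT and 8.39 in controls, and E1A spot a20 read 8.86 and 8.39. DCP_1_0 and DCP_22_0 were likewise close to E1A spots r60_1 and a22. The shares are therefore descriptions, and the name of the bright corner spots states no target. DCP spots also changed against their own 0 spot (-0.93 in the mean of 6). A different amount of added spike RNA cannot be set aside by this, since the response of dim spots to that amount was not tested. How far a difference in array processing or an effect of OMT accounts for the RNA probe calls cannot be told apart, since each array set holds 1 treatment. The 6 arrays allow 10 splits, too few for a share under 0.05. After joint normalization 1 of them, the real one, gave 68940 calls, against at most 0 in the others. Each other split mixes OMT and control arrays, so the group difference itself enters the spread. Few calls there were thus built in and give no baseline.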

How the results depend on the processing

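The counts for circRNA probes under settings other than the replicate block and the dimmer 50% left out, the joint normalization combined with that filter or with the block, and the circRNA minus cluster difference were chosen after seeing the data.

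The number of called probes (81099) stayed within 1.5 times under every setting run. The split by direction did not. As deposited 13808 probes were higher and 67291 lower. Joint normalization gave 36149 and 32791, with the dimmer 50% of probes left out 34296 and 28218, and with the replicate block 30270 and 27445. Centring on the 75th percentile gave 74360 and 35517. For circRNA probes (2895 higher, 29638 lower), these 4 settings gave 10525 and 16165, 11292 and 15483, 8450 and 13640, and 14783 and 16958. These moves follow from the scalings: joint normalization gives both groups one distribution, and centring moved the median change of all probes from -0.36 to 0.44. What made the deposited distributions differ between the groups cannot be told here. An adjusted p below 0.01 left 8657 higher probes (1772 circRNA), and an added 2-fold threshold 6532 (805 circRNA), which follows from the stricter thresholds.

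Leaving out 1 array gave 67955 to 77113 called probes. The circRNA minus cluster difference of -0.40 ranged from -0.42 to -0.37 without 1 array and was -0.40 with the deposited values. Centring gives the same value as the deposited levels by construction, since it shifts both families on an array alike. The 8 named probes gave 120 values under other settings, and all 120 kept direction and an adjusted p below 0.05. Since these probes were selected for large changes on the same arrays, the count is not an independent check.

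Replicate numbers did not pair the samples. Over the 87537 probes with a mean above the median, deviations of same-numbered arrays correlated at 0.03, -0.11 and 0.01. Of the 3 OMT arrays, 0 correlated best with the control array of its own number. With the replicate block, 71508 probes were called (11456 higher, 60052 lower), and no count moved by over 1.5 times.

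The alternatives for the gene-level test and the gene lists were not run, since no RNA probe had a gene name in the tables used here. Signal over background limits the low probes: 60.5% of RNA probes lay above the dark corner on all OMT arrays and 63.8% on all control arrays.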

Other observations

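The split of called probes by direction, as deposited and after joint normalization, came from fits fixed before the data were examined. The other tests in this part were chosen after the results they bear on had been seen. Several groupings of the probes by parts of their IDs were looked at before those given here. The numbers inside the IDs have no stated meaning in the sources used here. Probes are not independent replicates, so correlations across probes are descriptions.

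Falls outnumbered rises among the largest changes. After joint normalization, 2444 probes were called and at least 8-fold lower in OMT and 952 at least 8-fold higher, and at 32-fold the counts were 163 and 24. As deposited they were 6695 and 308 at 8-fold, and 432 and 7 at 32-fold. CircRNA probes made up 1099 of the 8-fold falls and 58 of the 8-fold rises after joint normalization. They were 27.4% of all RNA probes and 35188 of the 77934 with a level of 4 or more. The share of circRNA probes among the 8-fold falls was above the first of these shares and near the second. The falls were not limited to that level, and their count alone does not show an excess of circRNA probes. Among the 8-fold rises, 58 of 952 was below both shares.

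Changes followed the probe IDs. CircRNA probes carry a next-to-last number from 0 to 16. Among 13711 of them with a level from 6 up to 8, Spearman's rho between that number and the change after joint normalization was -0.30, where the 6 differences between replicates of one group gave at most 0.09 in size. The median change went from 0.37 at 0 through -0.003 at 7 to -0.42 at 16, and was lowest at 15 with -0.51. Probes numbered 16 minus probes numbered 0 gave -0.53 ± 0.04 on OMT arrays and 0.27 ± 0.01 on control arrays (SD, n = 3), a difference of -0.80 with an exact two-sided permutation p of 0.1. Cluster probes of level 4 or more changed with the cluster number (rho -0.23, against at most 0.12 between replicates), and with their own next-to-last number in the direction opposite to that of circRNA probes (rho 0.20, against at most 0.11). Over 5 equal bins of these probes, from low to high cluster numbers, the median change was 0.60, 0.51, 0.39, 0.22 and -0.15, and the share of probes at least 8-fold lower was 0.55%, 0.79%, 1.91%, 2.53% and 6.06%.

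Most called probes were lower in OMT as deposited (83.0%). Normalization of each group by itself leaves any difference in brightness between the array sets in the values, and a true fall of most RNAs after OMT would look alike, so these cannot be told apart here. After joint normalization 47.6% of the called probes were lower, but that step gives both groups one distribution and so balances the split whatever the cause. The 10 E1A spike spots, which would mark the scale, had a median change of 0.16 as deposited with an SD of 1.14 between spots, too wide to decide. As deposited, 1 of the 10 splits of the arrays, the real one, gave 81099 calls, against at most 0 in the others. The other splits mix OMT and control arrays, so few calls there were built in, and 10 splits are too few for a share under 0.05.

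CircRNA probes stood below cluster probes of the same level in OMT, with Agilent catalogue probes between them at levels from 6 up to 8. A change of scale over the whole array would shift probes of one level alike, whereas the families differed by -0.40 at levels from 6 up to 8, with SDs of 0.05 in OMT and 0.01 in controls. A hybridisation difference between the array sets stays open. The DCP spots considered had a last number of 5 or more and lay above the dark corner on all arrays. On OMT arrays, 6 of 6 had lower signal against their own 0 spot. The mean difference was -0.93 after joint normalization (-4.44 ± 0.09 against -3.51 ± 0.05, SD, n = 3), with single spots from -0.37 to -1.84. As deposited it was -1.13 (from -0.16 to -2.21). Spots of one series share a 0 spot and so are not independent. No source states that this number counts mismatches, and each array set holds 1 treatment. Lower circRNA abundance after OMT stays open as well, since circRNA probes numbered 0 differed from cluster probes by 0.089 and those numbered 16 by -0.71, and whether a low number marks a probe that also reads linear RNA is not known here. If the number marks where the back-splice junction lies in the probe, a loss of circular RNA and a loss of partly matched linear RNA could give the same trend.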
